A study of Mus musculus with 6 samples.

How the data were processed

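Cy3-labelled cRNA made from total RNA of whole mouse hearts was hybridised to 1-colour Agilent mouse 8x60K expression arrays, 1 array per mouse. Per the labels' protocols, male C57BL6 mice aged 10 weeks were starved for 16 h, given 20 mg/kg lipopolysaccharide (LPS) into the peritoneum, treated with saline or recombinant human thrombomodulin (rhTM) at 3 and 24 h, and sampled at 30 h. The groups were 3 saline mice and 3 rhTM mice, assigned from the sample titles, and no array of a mouse without LPS was used here.

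The scanner files hold intensity values as the authors deposited them. Per the file headers they were made with Agilent Feature Extraction 10.7.3.1 on a grid of build mm9, while the submitters' processing notes name version 9.1. The processed signal in those files is a background-corrected spot intensity, per the file headers, and it was not normalised between arrays. The deposited value table holds log2 values whose scale, centring and baseline are not given in the sources used here. Set against the scanner values, each of its columns equalled the log2 processed signal minus the array's 75th percentile and minus a baseline per probe. That baseline was the same for arrays of 1 slide (SD of the difference 1.9e-05 between saline 1 and 2, and up to 3.8e-07 between saline 3 and the rhTM arrays) and differed between slides (SD 0.825 between saline 1 and saline 3, over 55937 probes). The table's column medians were -0.02, -0.16 and 0.10 for saline 1, 2 and 3 and -0.08, 0.03 and 0.09 for rhTM 1, 2 and 3. It was used only as an alternative, with the caveat that its values are not on 1 baseline across slides.

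Each array held 59305 spots besides controls, of which 54.8% to 62.8% were well above background and 0 were saturated. The 75th percentile of the processed signal was 732 and 671 in saline 1 and 2, 394 in saline 3, and 463, 466 and 412 in rhTM 1, 2 and 3. The median coefficient of variation of replicated probes within an array was 2.73% to 3.46%. The r2 of the spike-in controls was 0.990 and 0.987 in saline 1 and 2 and 0.845 to 0.881 in the other arrays. The number of arrays limits the precision of every value below. The array identifiers and scan records place saline 1 and 2 on slide 1 (scan 1), and saline 3 with all rhTM arrays on slide 2 (scan 2). Every comparison was therefore repeated with the slide as a block. In that fit the estimate for a gene equals its mean over the rhTM arrays minus saline 3, so the blocked value and the within-slide value are the same number and rest on 1 saline array.

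For the comparison, the log2 processed signal minus the 75th percentile of its array was used. Spots of 1 probe were averaged, control spots and 368 of 56605 probes with outlier flags were left out, and probes were named through their transcript accession in a RefSeq table of assembly GRCm38.p6. Of the probes left, 32789 matched a gene symbol and 23448 did not. No coordinates are given because the table's assembly is not the build of the grid. Of 22815 genes with a symbol, each was represented by its probe with the highest mean signal over all 6 arrays, and the 14701 genes whose probe was well above background on all 3 arrays of at least 1 group were tested. Among them 4920 had 2 or more kept probes, and the change of those other probes is given where one went the other way or changed by much less. Where a probe was not well above background on any array of a group, the fold is a bound. It is the brighter group's mean against, per array of the dimmer group, the higher of the lowest signal well above background and the probe's own signal.

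Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) and Benjamini-Hochberg adjustment over all genes tested, with calls at an adjusted p under 0.05. The 54 gene lists, the comparison, the rule for named genes and all but 1 of the alternatives were chosen before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Beside camera, fry and an exact two-sided permutation test of each list's mean per array were run, and the latter cannot give a p below 0.1 with 3 arrays against 3. Named genes are the 12 largest called changes per direction with the groups apart, the higher group well above background and a plain gene symbol, up to 4 members of each list by p, and 23 genes of the thrombomodulin, endothelial, inflammatory and cardiac stress systems.

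The same numbers 1 to 3 occur in both groups of the labels. The deviations of same-numbered arrays from their group means correlated at 0.319, 0.235 and 0.372 across genes, which are not independent replicates. Arrays with different numbers were not compared in this way, and a likeness of saline 3 and rhTM 3 alone can raise all 3 values. The correlations therefore cannot establish a pairing, and the fit with the number as a block serves only as an alternative. The labels name 6 separate mice and no shared litter or day. The fit with the number as a block is given where it changes a call.

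Alternatives covered quantile normalisation, centring on the median of the genes tested, normexp background correction (offset 50) with quantile normalisation, the deposited value table, 2 other filters, 2 other summaries of probes, slide and replicate blocks, the shared slide alone, array weights, another variance model, other thresholds, other list tests and leaving out each array. The normexp alternative used the median spot signal because the scanner files hold no mean signal. Leaving out genes with disagreeing probes was added after the data were seen. The pipeline was tested on simulated data with known changes in 14701 genes, 3 arrays against 3. It recovered 10.8%, 85.2%, 94.8% and 97.6% of genes changed by 1, 2, 3 and 4 on the log2 scale, with 8.2 unchanged genes called per run on average. The simulated noise was independent between genes, with no slide effect and no outlying array. These rates therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.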

Results

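Gene expression was measured in the hearts of 6 mice 30 h after an injection of lipopolysaccharide (LPS), the bacterial endotoxin used to model septic inflammation. From 3 h on, 3 of the mice had received saline and 3 recombinant human thrombomodulin (rhTM), a soluble form of the endothelial thrombin receptor that promotes activation of protein C. The comparison addresses how rhTM given after LPS altered the heart's transcripts in a study of myocardial injury in endotoxemia. Every mouse had received LPS, so each value below compares rhTM with saline after LPS and none compares with an untreated heart. Of 59305 spots per array besides controls, 56.7%, 58.9% and 54.8% were well above background in saline 1, 2 and 3 and 62.8%, 60.6% and 57.1% in rhTM 1, 2 and 3. Values are log2 signals relative to the 75th percentile of their array, and changes are rhTM minus saline with the SE of the fit (n = 3 and 3).

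The arrays did not form 2 tight groups. Across genes, which are not independent replicates, saline 1 and 2 correlated at 0.987 and rhTM 1 and 2 at 0.994. Saline 3 correlated at 0.965 with rhTM 3, at 0.942 and 0.939 with saline 1 and 2, and at 0.924 and 0.923 with rhTM 1 and 2. The first principal component, with 56.1% of the variance, placed all saline arrays on one side and all rhTM arrays on the other. The second, with 30.4%, separated saline 3 and rhTM 3 from the other arrays. Saline 1 and 2 were on slide 1, and saline 3 shared slide 2 with the rhTM arrays.

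**Figure D1:**
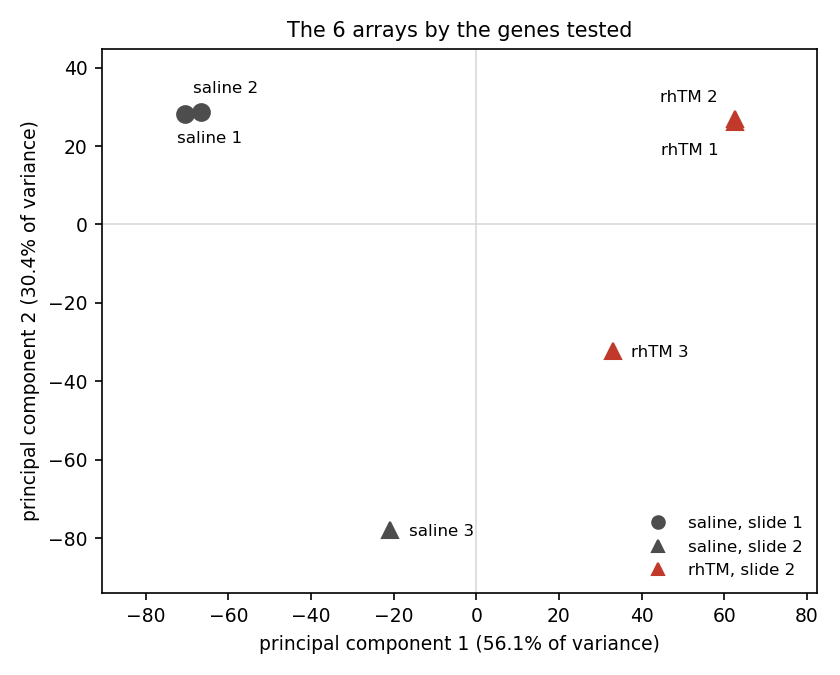
Scores of the 6 arrays on the first and second principal components of the 14701 genes tested (axes in score units, with the percent of variance), with colour for the group and marker shape for the slide. The saline arrays lie at -70.5, -66.6 and -20.9 on the first component and the rhTM arrays at 62.6, 62.5 and 33.0, and saline 3 lies lowest on the second at -78.0.

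The 12 largest decreases with rhTM included a granulocyte cytokine, an adhesion receptor of leukocytes and a neutrophil surface protein. Slc6a12, a betaine and GABA transporter, fell by 4.97 ± 0.95, a size that depends on background, since its probe was well above it on 1 of 3 rhTM arrays. Csf3, the cytokine that drives granulocyte production, was at least 8.03-fold lower, since its probe was not well above background on any rhTM array. Selp, the endothelial and platelet adhesion receptor P-selectin, fell by 4.06 ± 0.83 (16.7-fold) and its other probes differed by -3.33 and -1.98. Cd177, a neutrophil surface protein, was at least 2.7-fold lower, Fosl1, an AP-1 transcription factor, at least 3.49-fold, and Sostdc1, a BMP and Wnt antagonist, at least 4.73-fold. Other large decreases were in Star, the steroidogenic cholesterol transporter (-3.35 ± 0.62), Slc10a6 (-3.14 ± 0.62), Serpina3j (-2.98 ± 0.59), Itgb3, the integrin beta-3 chain (-2.90 ± 0.43), and Kcne4, a potassium channel subunit (-2.63 ± 0.51). Against saline 3 on the same slide these genes differed by -5.84 to -2.29. Slc6a12, Selp, Slc10a6, Serpina3j, Itgb3, Sostdc1 and Kcne4 no longer passed with the slide as a block (adjusted p 0.0520 to 0.132). In the fit with the replicate number as a block, Slc6a12, Selp and Serpina3j no longer passed (adjusted p 0.0536 to 0.0659).

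The 12 largest increases were in genes whose signal was low in saline hearts (mean -6.93 to -2.80). They were Nat3, an arylamine acetyltransferase (6.45 ± 1.31), Cfap54, a cilium protein (5.87 ± 1.03), Lyzl1 (5.55 ± 0.80), Itga10, the integrin alpha-10 chain (5.52 ± 0.92), Scgb1b7 (5.32 ± 0.74), Cox7b2 (5.19 ± 0.71) and Iqck (5.18 ± 0.71). Probes of Nat3, Cfap54, Lyzl1 and Scgb1b7 were well above background on 1 of 3 saline arrays, so that the sizes of their changes depend on background. Olfr429, an odorant receptor, Defb7, a defensin, S100z, Nexmif and Kap were not well above background on any saline array and were at least 11.3-fold, 17-fold, 9.16-fold, 14.4-fold and 11.1-fold higher. Against saline 3 the 12 genes differed by 3.20 to 4.85. Itga10 was the single one of the 12 with another kept probe, and that probe differed by -0.12. Over all 83 genes called higher by over 8-fold, saline 3 lay a median of 1.81 above saline 1 and 2. For the 8 of them with other kept probes, those probes changed by a median of 0.03, against 4.41 for the called ones. Signal of single probes or the slide may thus contribute to these increases, and neither was told apart from an effect of rhTM. Nat3, Cfap54 and Itga10 no longer passed once the replicate number was a block (adjusted p 0.0507 to 0.0584).

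In all, limma called 405 genes higher and 355 lower with rhTM among 14701 tested, 373 and 297 of them by at least 2-fold. The genes called higher lay at a median level of -1.84, against 0.31 for all genes tested, and 19.8% of them carried clone-type symbols, against 7.80% of all tested and 1.97% of those called lower. In 35.7% of genes the rhTM and saline arrays did not overlap. Random labels on exchangeable arrays would give 10% on average, but the share in other splits was not computed. Since saline 1 and 2 were on another slide, the excess cannot be read as an effect of rhTM. With the slide as a block 563 and 287 genes were called, 224 and 112 of them in both fits. All 405 and 355 genes kept their direction within the slide, which is no independent check, since saline 3 was used to call them. The counts rested on single arrays: 3007 genes were called higher and 2808 lower without saline 3, 2 and 0 without saline 1, 55 and 3 without saline 2, 0 and 0 without rhTM 1 (limma, 1271 and 1314 at unadjusted p under 0.05) and 2 and 0 without rhTM 2. Without rhTM 3 they were 382 and 512. Centring the arrays on the median of the genes tested gave 483 higher and 268 lower, so that 64.3% of calls were higher, against 53.3%. Of the 76 called genes among the 241 named ones, 34 were also called with the slide as a block and 45 with the replicate number as a block.

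Among lists of genes fixed beforehand, camera called 4 of 54 higher and 11 lower at adjusted p under 0.05. With an estimated correlation none of the 15 was called (adjusted p = 0.808 for each). The lists called lower included acute phase proteins, NF-kB cytokines and neutrophil markers, but not chemokines, complement or Toll-like receptor components. Those called higher were class II antigen presentation, oxidative phosphorylation, the tricarboxylic acid cycle and T and NK cell markers. With the slide as a block 7 and 12 were called, 3 and 8 of them in both fits, and with the replicate number as a block 7 and 15. Fry, which tests whether a list's genes move one way on balance, called none (lowest adjusted p 0.102). The exact permutation test gave an unadjusted p = 0.2 for the NF-kB, interferon response, class I and T and NK cell lists. For neutrophil markers and the tricarboxylic acid cycle the exact permutation test gave an unadjusted p = 0.3. For the other called lists the exact permutation test gave p = 0.1, the lowest it can give. No list was called with an estimated correlation in the blocked fits (lowest adjusted p 0.866 with the slide and 0.652 with the replicate number).

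**Figure D2:**
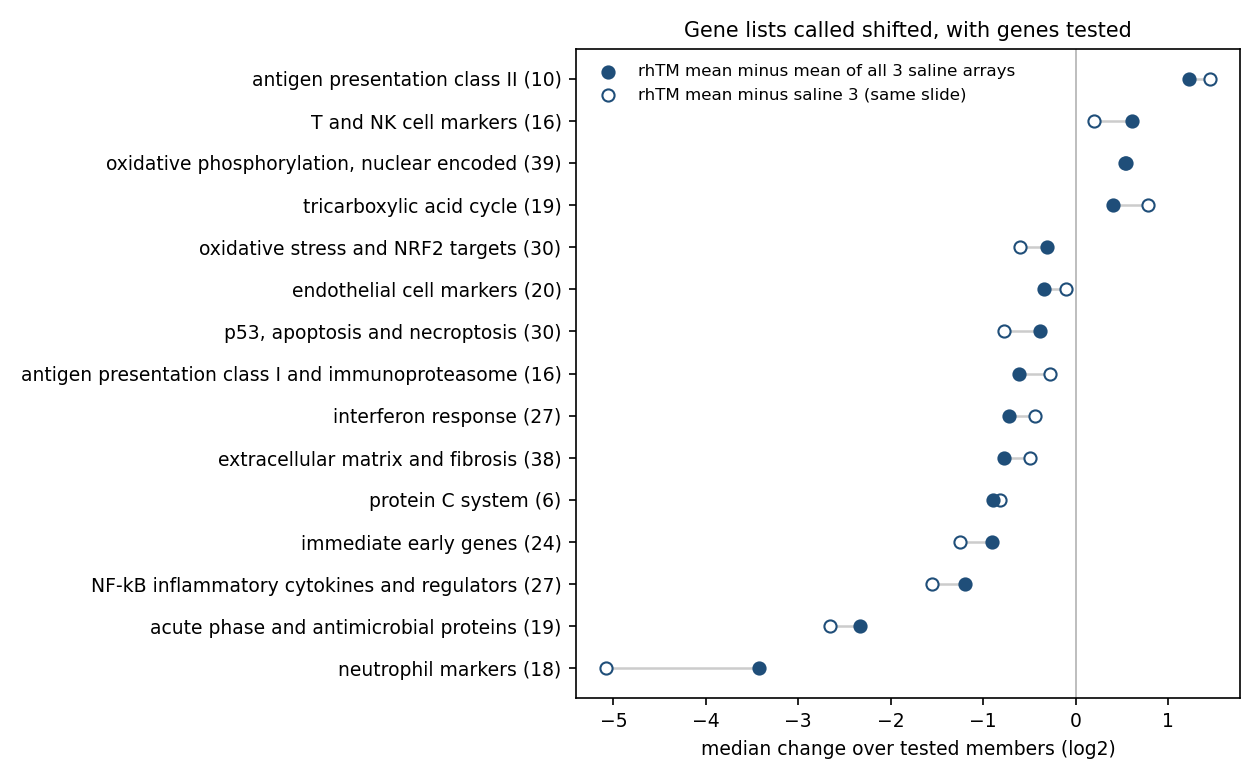
Median change over the tested members (log2, horizontal axis) of the 15 lists that camera called, with the number of tested genes in parentheses. Filled points are rhTM minus all saline arrays and open points rhTM minus saline 3 on the same slide, and neutrophil markers lie lowest in both, at -3.42 and -5.08.

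Acute phase and antimicrobial proteins, secreted early in infection, lay lower, with a median of -2.34 over 19 genes (camera adjusted p = 7.38e-06; adjusted p = 0.808 with an estimated correlation). The list's mean signal was 1.24, 1.47 and 2.20 in saline 1, 2 and 3 and -1.96, -2.09 and 1.13 in rhTM 1, 2 and 3, so that rhTM 3 lay near saline 1. Same-numbered arrays differed by -3.21, -3.56 and -1.07, but the numbers establish no pairing, here or for the lists below. All 19 members lay lower in the group means, 0 passed over all genes and 11 passed adjusted over the list alone. The iron-binding lipocalin Lcn2 lay at 8.63 ± 0.17 in saline and 5.63 ± 1.72 in rhTM hearts (SD, n = 3, adjusted p = 0.0753). Serpina3n (-3.17 ± 0.74, adjusted p = 0.0581), Serpina3m (-4.53 ± 1.10, 0.0649) and ceruloplasmin, Cp (-2.18 ± 0.48, 0.0528, its other probes -1.58 to -0.09), also missed the threshold. Cytokines and regulators of the NF-kB pathway lay lower, with a median of -1.19 (27 genes, adjusted p = 9.44e-06; 0.808 with an estimated correlation). Its mean was 0.28, 0.71 and 1.58 in saline 1, 2 and 3 and -0.91, -1.24 and 0.39 in rhTM 1, 2 and 3, so that rhTM 3 lay above saline 1. Same-numbered arrays, not established as pairs, differed by -1.19, -1.95 and -1.19. The 3 called members were Csf3, Csf1 (-1.32 ± 0.24) and the NF-kB subunit Relb (-1.62 ± 0.33). Adjusted over the list alone, 16 were lower and 1 higher. Il6, well above background on 2 of 3 rhTM arrays, differed by -4.72 ± 1.60 (adjusted p = 0.114) and Il1b by -2.57 ± 1.68 (0.325). Tnf differed by 0.94 ± 0.25 (0.0734), and its probes disagreed, the other one differing by -2.63. Against saline 3 the list medians were -2.66 and -1.56, both still called. Blocking on the slide, Csf1 and Relb no longer passed (adjusted p 0.0827 to 0.102). When the replicate number was a block, Csf1 and Relb no longer passed (adjusted p 0.0577 to 0.0604). With the replicate number as a block, Il6 passed (adjusted p 0.0390).

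Neutrophil markers had the lowest median of any list, -3.42 over 18 genes (adjusted p = 7.60e-04; adjusted p = 0.808 with an estimated correlation) and -5.08 against saline 3. Of the 18 members 17 lay lower and 1, Cd177, was called, with 2 adjusted over the list alone. The list's mean was 0.52, 1.48 and 3.29 in saline 1, 2 and 3 and -2.35, -3.01 and 1.76 in rhTM 1, 2 and 3, so that rhTM 3 lay above saline 1 and 2. Same-numbered arrays, not established as pairs, differed by -2.87, -4.49 and -1.52. The calprotectin gene S100a8 lay at 3.92, 5.26 and 8.42 in saline 1 to 3 and at 1.01, -0.79 and 7.17 in rhTM 1 to 3 (adjusted p = 0.310). S100a9 differed by -3.52 ± 2.01 (adjusted p = 0.270). Lrg1, a secreted glycoprotein, differed by -2.34 ± 0.51 (adjusted p = 0.0526). Without saline 3 the list was no longer called (median -2.56), nor among genes well above background on all 6 arrays (median -2.87). Chemokines (-0.71, adjusted p = 0.0615) and neutrophil granule and extracellular trap genes (-1.12, 0.0815) were not called. Both were called with the slide as a block (0.0370 and 0.0215) and with the replicate number as a block (0.0272 and 0.00698). With the correlation estimated, neither call held (adjusted p = 0.866 and adjusted p = 0.652 to 0.704 with an estimated correlation in the slide and replicate fits). Among their members Cxcl1 differed by -3.22 ± 1.14, Cxcl5 by -4.36 ± 1.44, Cxcl3, well above background on 1 of 3 rhTM arrays, by -4.35 ± 1.65 and Ccl2 by -1.75 ± 0.98. None passed the threshold (adjusted p 0.111 to 0.264). The elastase gene Elane lay the other way (2.01 ± 0.58, 0.0860). Cxcl5 and Cxcl3 passed with the replicate number as a block (adjusted p 0.0390 to 0.0464).

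**Figure D3:**
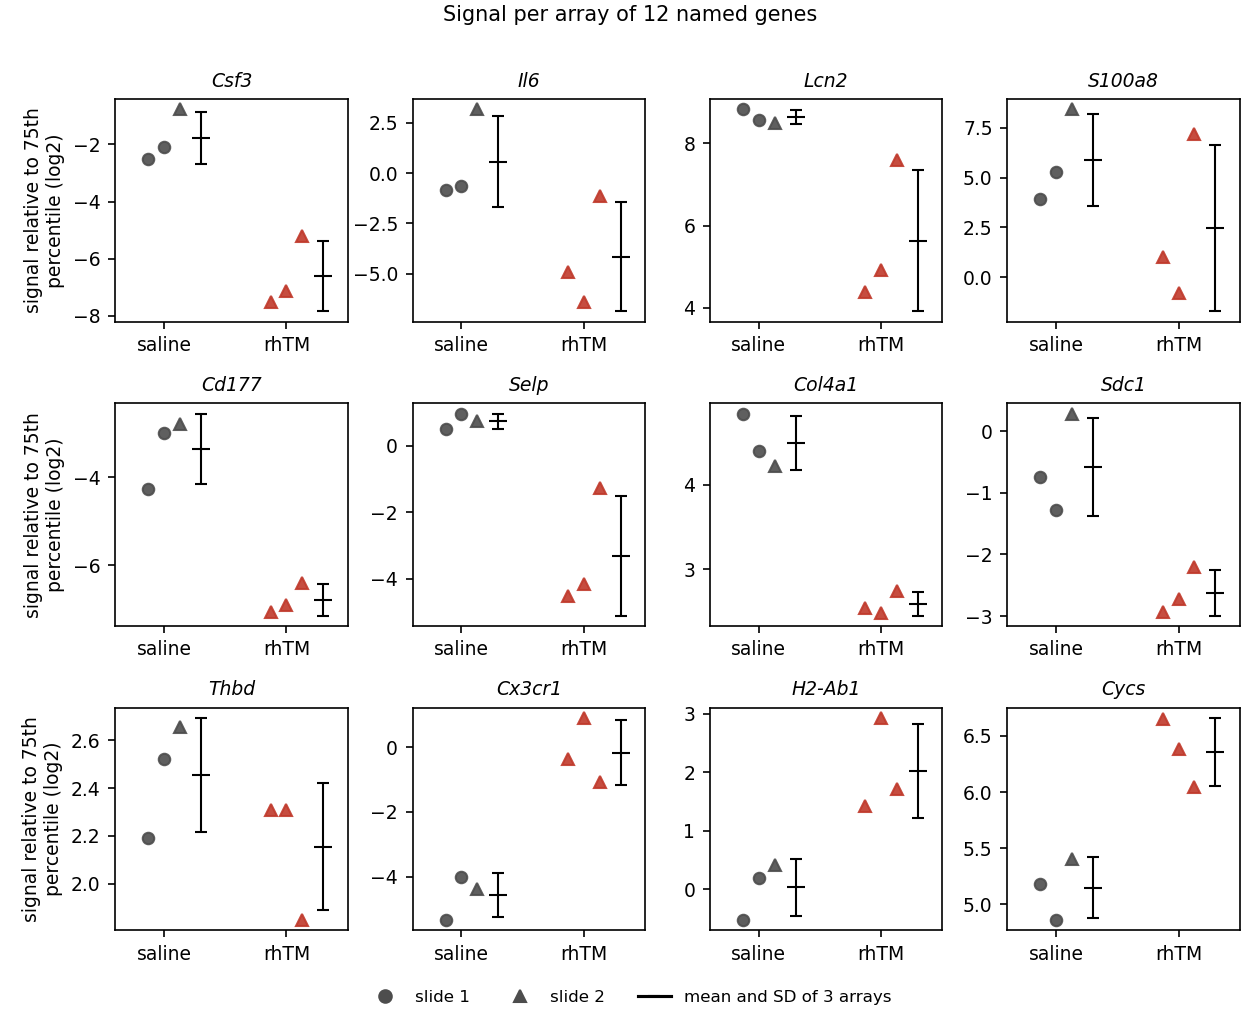
Log2 signal relative to the 75th percentile of the array (vertical axes, each with its own range) of 12 named genes in the 3 saline and 3 rhTM hearts, with circles for slide 1, triangles for slide 2 and bars for the mean and SD. For S100a8 and Lcn2, rhTM 3 lies above rhTM 1 and 2, while for Col4a1 the rhTM arrays (mean 2.59) lie together below the saline arrays (mean 4.49).

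Interferon response genes and genes of class I antigen presentation, which display peptides to cytotoxic T cells, were also shifted lower, but less so on the shared slide. The interferon list had a median of -0.72 (27 genes, adjusted p = 7.84e-04; 0.808 with an estimated correlation). Its mean was 1.22, 0.88 and 0.76 in saline 1, 2 and 3 and 0.08, 0.02 and 0.88 in rhTM 1, 2 and 3, and same-numbered arrays differed by -1.14, -0.86 and 0.12. Its members lay lower in 24 cases and 1 was called, the RNA sensor Ddx58 (-1.26 ± 0.27, its other probes -0.97 and -0.39), or 2 adjusted over the list alone. The antiviral gene Oasl2 narrowly missed the threshold (-1.44 ± 0.32, adjusted p = 0.0535). The class I list had a median of -0.61 (16 genes, adjusted p = 0.0224; 0.808 with an estimated correlation). Its mean in rhTM 3 (2.99) also lay above that in saline 3 (2.93). It had no called member, with H2-D1 at -1.02 ± 0.32 (adjusted p = 0.0994) and Tapbp, the peptide-loading chaperone tapasin, at -1.52 ± 0.40 (0.0731). Both lists lost their call with the slide as a block (medians -0.44 and -0.28, adjusted p 0.0875 and 0.420), the class I list also without rhTM 2 (median -0.56) and with the deposited table (-0.44). GTPases and chemokines induced by interferon gamma had a median of -0.32 and were not called (adjusted p = 0.636). Toll-like receptor and inflammasome components were not called either (median 0.05 but mean -0.23, adjusted p = 0.592), though Myd88, the adaptor of most Toll-like receptors, fell by 1.54 ± 0.29 (adjusted p = 0.0430). Against saline 3 that list's median was -0.42, with 18 members lower and 6 higher. In the fit with the slide as a block, Ddx58 and Myd88 no longer passed (adjusted p 0.0934 to 0.109). Ddx58 and Myd88 no longer passed once the replicate number was a block (adjusted p 0.0563 to 0.0761).

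The heart's own thrombomodulin gene, Thbd, did not differ detectably (2.46 ± 0.24 in saline and 2.16 ± 0.27 in rhTM hearts, SD, n = 3, adjusted p = 0.387). The protein C system, which inactivates clotting factors after thrombomodulin binds thrombin, lay lower, with a median of -0.90 over 6 genes (adjusted p = 0.0224; 0.808 with an estimated correlation), and its median was -0.82 against saline 3. Its called member was Pros1, the protein C cofactor protein S (-1.09 ± 0.21, adjusted p = 0.0430), and 3 members passed adjusted over the list alone. The list also held Sphk1 (-2.41 ± 0.67, adjusted p = 0.0811, -3.66 against saline 3) and F2r (-0.71 ± 0.20, 0.0873), neither called. The protein C receptor gene Procr differed by -1.15 ± 0.51 (adjusted p = 0.183), and without saline 3 the list was not called (median -0.73). Its call was also lost with no filter on dim probes (median -0.23) and with array weights (-1.07). Coagulation and fibrinolysis genes had a median of -0.71 (adjusted p = 0.0568; 0.0292 with the slide as a block and 0.0290 with the replicate number). With the correlation estimated, neither blocked call held (adjusted p = 0.866 and adjusted p = 0.652 with an estimated correlation in the slide and replicate fits). Plat, the tissue plasminogen activator, fell by 1.23 ± 0.21 (adjusted p = 0.0352). Tissue factor, F3, differed by 1.12 ± 0.44 (adjusted p = 0.146). Blocking on the slide, Pros1 and Plat no longer passed (adjusted p 0.0559 to 0.0804). When the replicate number was a block, Pros1 and Plat no longer passed (adjusted p 0.0524 to 0.0638). With the replicate number as a block, Procr and Sphk1 passed (adjusted p 0.0390 to 0.0494).

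In the endothelium, adhesion and activation genes lay lower without passing as a list (median -0.64, 23 genes, adjusted p = 0.0568), and Selp was the called member. The adhesion receptors Icam1 (-2.65 ± 0.71, adjusted p = 0.0764), Vcam1 (-1.48 ± 0.37, 0.0680) and Sele (-2.51 ± 0.77, 0.0975), well above background on 1 of 3 rhTM arrays, missed the threshold. Of the angiopoietin axis, Angpt2 differed by 0.33 ± 0.39 and Tek by -0.08 ± 0.31, neither called (adjusted p 0.580 and 0.875). Glycocalyx genes, which build or shed the sugar coat of the endothelium, had a median of -0.19 over 44 genes (adjusted p = 0.113), and 1 passed, the core protein syndecan-1, Sdc1 (-2.04 ± 0.43, adjusted p = 0.0478, -2.91 against saline 3). Sdc4 differed by -1.48 ± 0.42 (adjusted p = 0.0835). Junction genes were not called (median -0.17, adjusted p = 0.492) and the VE-cadherin gene Cdh5 stood at 0.02 ± 0.19 (0.963). Markers of endothelial cells were called lower (median -0.34, 20 genes, adjusted p = 0.0364; 0.808 with an estimated correlation) with no called member. The call was lost with the slide as a block (median -0.11, adjusted p = 0.420) and without any one of saline 1, rhTM 2 and rhTM 3 (medians -0.28, -0.41 and -0.30). It was also lost with quantile normalisation, normexp, the deposited table and the stricter filter (medians -0.40, -0.37, -0.25 and -0.34). Selp no longer passed with the slide as a block (adjusted p 0.109). In the fit with the slide as a block, Sdc4 passed (adjusted p 0.0361). Selp no longer passed once the replicate number was a block (adjusted p 0.0536). Blocking on the replicate number, Sdc4 passed (adjusted p 0.0403).

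Genes of class II antigen presentation, by which macrophages and dendritic cells show peptides to helper T cells, were shifted higher by 1.23 over 10 genes (adjusted p = 0.00309; 0.808 with an estimated correlation) and by 1.45 against saline 3. The class II regulator Ciita, well above background on 1 of 3 saline arrays, rose by 2.64 ± 0.46 (adjusted p = 0.0379). Adjusted over the list alone, 6 members passed. H2-Ab1 (1.99 ± 0.45, adjusted p = 0.0549) and H2-Aa (2.10 ± 0.46, 0.0528) narrowly missed the threshold over all genes. Monocyte and macrophage markers were not called as a list (median 0.29, 24 genes, adjusted p = 0.0568). Its 3 called members, all higher, were Cx3cr1, the fractalkine receptor, well above background on 1 of 3 saline arrays (4.40 ± 0.57, adjusted p = 0.0244), Ms4a7 (2.16 ± 0.33) and the transcription factor Maf (1.52 ± 0.27). Cx3cr1 was among the genes called higher by over 8-fold, for which signal of single probes stays possible. T and NK cell markers were called higher (median 0.61, 16 genes, adjusted p = 0.0262; 0.808 with an estimated correlation), with no called member. Their mean was -2.76, -2.33 and -1.77 in saline 1, 2 and 3 and -2.03, -1.71 and -1.02 in rhTM 1, 2 and 3, and same-numbered arrays differed by 0.73, 0.62 and 0.76. They lost that call with the slide as a block (median 0.20, adjusted p = 0.579) and without saline 1 or rhTM 3 (medians 0.32 and 0.30). It was also lost with normexp, the deposited table and the stricter filter (medians 0.30, 0.28 and 0.43). Genes of tissue repair and alternatively activated macrophages were not called (median 0.04, adjusted p = 0.702), although Il4ra fell by 2.31 ± 0.41 (its other probe -0.67). When the slide was a block, Ciita, Cx3cr1, Ms4a7, Maf and Il4ra no longer passed (adjusted p 0.0549 to 0.0910). With the replicate number as a block, Ciita and Il4ra no longer passed (adjusted p 0.0547 to 0.0557). H2-Ab1 passed with the replicate number as a block (adjusted p 0.0489).

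Genes of mitochondrial energy production lay higher in rhTM hearts. Nuclear genes of oxidative phosphorylation were shifted by a median of 0.54 over 39 genes (adjusted p = 7.38e-06; 0.808 with an estimated correlation), 35 of them higher, and by 0.54 against saline 3. The 4 called members were Ndufa8 (1.51 ± 0.29) and Ndufb3 (0.87 ± 0.18) of complex I, Sdhd of complex II (0.94 ± 0.20) and cytochrome c, Cycs (1.21 ± 0.24). Adjusted over the list alone, 8 passed. Genes of the tricarboxylic acid cycle were shifted by 0.40 (19 genes, adjusted p = 0.0206; 0.808 with an estimated correlation) with no called member, and by 0.78 against saline 3. Its mean was 5.65, 5.64 and 5.06 in saline 1, 2 and 3 and 6.11, 6.05 and 5.45 in rhTM 1, 2 and 3, and same-numbered arrays differed by 0.47, 0.41 and 0.38. That list missed the threshold with quantile normalisation, normexp and every probe tested by itself (medians 0.24, 0.26 and 0.34) and without any one of saline 3, rhTM 1 and rhTM 2 (medians 0.28, 0.30 and 0.32). Catabolism of ketones and branched-chain amino acids had a median of 0.27 (adjusted p = 0.0574; 5.53e-05 with the slide and 0.0389 with the replicate number as a block). Neither blocked call held once the correlation was estimated (adjusted p = 0.866 and adjusted p = 0.652 with an estimated correlation in the slide and replicate fits), and 1 member was called, Mccc2 (1.34 ± 0.27). The mean of the ketone and branched-chain list was 2.76, 2.84 and 2.07 in saline 1, 2 and 3 and 3.16, 3.13 and 2.59 in rhTM 1, 2 and 3. Saline 3 thus lay lowest there. Fatty acid oxidation and PPAR targets were not called as a list (median -0.01, adjusted p = 0.558). Of its members, Cpt1a, which admits fatty acids to mitochondria (-1.67 ± 0.29), and the uncoupling proteins Ucp2 (-1.89 ± 0.36) and Ucp3 (-1.84 ± 0.36) fell. Glycolysis and glucose uptake genes were not called (median -0.13, adjusted p = 0.362). In the fit with the slide as a block, Ndufa8, Ndufb3, Sdhd, Cycs, Mccc2, Cpt1a, Ucp2 and Ucp3 no longer passed (adjusted p 0.0667 to 0.111). Ndufa8, Ndufb3, Sdhd, Cycs, Ucp2 and Ucp3 no longer passed once the replicate number was a block (adjusted p 0.0561 to 0.0706).

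Of the contractile and electrical genes of the heart muscle, few passed. Sarcomere genes had a median of 0.43 (25 genes, adjusted p = 0.0626), 0.91 with the slide as a block (adjusted p = 5.48e-06; 0.0290 with the replicate number). The sarcomere list's mean was 6.12, 6.25 and 5.10 in saline 1, 2 and 3 and 6.35, 6.39 and 5.89 in rhTM 1, 2 and 3. Saline 3, the single saline array behind the blocked value, thus lay lowest. Lmod2, which sets thin filament length, rose by 1.17 ± 0.18. Calcium handling and ion channel genes had a median of 0.50 (not called), 0.64 with the slide as a block (adjusted p = 2.31e-04; 0.0290 with the replicate number). None of the blocked calls held once the correlation was estimated (adjusted p = 0.866 and adjusted p = 0.652 to 0.704 with an estimated correlation in the slide and replicate fits). The calcium handling list's mean was also lowest in saline 3, at 1.63, 1.87 and 0.91 in saline 1, 2 and 3 and 2.11, 2.03 and 1.59 in rhTM 1, 2 and 3. Its 2 called members, both higher, were phospholamban, Pln, which restrains the calcium pump (1.35 ± 0.28), and the channel subunit Kcne1 (2.02 ± 0.37). The fetal and stress program was not called (median -0.34, adjusted p = 0.362), with Fhl1 (-1.42 ± 0.20) and filamin C, Flnc (-1.95 ± 0.33), called lower. The natriuretic peptide genes Nppa (0.85 ± 0.34, adjusted p = 0.151) and Nppb (1.45 ± 0.91, 0.308) and the beta myosin gene Myh7 (0.82 ± 0.65, 0.411) did not pass. Blocking on the slide, Kcne1 no longer passed (adjusted p 0.0573).

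Matrix genes lay lower, with a median of -0.77 over 38 genes (adjusted p = 5.05e-04; 0.808 with an estimated correlation). Of them 5 were called, or 11 lower and 2 higher adjusted over the list alone. The basement membrane collagens Col4a1 (-1.90 ± 0.22, adjusted p = 0.0188) and Col4a2 (-2.14 ± 0.28) fell, as did the growth factor Tgfb2 (-1.92 ± 0.35, its other probe -0.83) and smooth muscle actin, Acta2 (-1.55 ± 0.24), whose other probes differed by -1.44 and 0.28. Immediate early genes, induced within minutes of a stimulus, were shifted by -0.90 (24 genes, adjusted p = 7.60e-04; 0.808 with an estimated correlation). The 4 called members were Fosl1, Ier2 (-1.19 ± 0.19), Ier3 (-1.69 ± 0.31) and Btg2 (-0.97 ± 0.20). Genes of p53 signalling and cell death were shifted by -0.38 (adjusted p = 0.0206; 0.808 with an estimated correlation). The cell cycle inhibitor Cdkn1a fell (-2.51 ± 0.46, its other probe -0.23) and Ccng1 rose (1.10 ± 0.22). NRF2 and oxidative stress targets had a median of -0.31 (adjusted p = 0.0224; 0.808 with an estimated correlation). Its called members were Gclm, a glutathione synthesis subunit (-1.32 ± 0.22), and G6pdx (-1.66 ± 0.28). Metallothioneins and metal handling genes were not called (median -0.49, adjusted p = 0.0568; 0.0290 with the replicate number as a block, and adjusted p = 0.652 with an estimated correlation in that fit). The zinc transporter Slc39a14 fell (-1.30 ± 0.27). Against saline 3 the 4 called lists had medians of -0.49, -1.25, -0.77 and -0.60, all called. The p53 and NRF2 lists were not called without saline 3 (medians -0.37 and -0.43). When the slide was a block, Acta2, Ier3, Btg2, Cdkn1a, Ccng1, Gclm and G6pdx no longer passed (adjusted p 0.0605 to 0.0985). With the replicate number as a block, Btg2, Cdkn1a, Ccng1 and Gclm no longer passed (adjusted p 0.0547 to 0.0668).

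Other lists of signalling, stress and growth genes did not pass. Angiogenesis signalling had a median of -0.17 (adjusted p = 0.362), with Notch1 (4.34 ± 0.56) and the apelin receptor Aplnr (1.89 ± 0.34) higher and Pgf, placental growth factor (-1.79 ± 0.29), and Notch4 (-1.06 ± 0.22) lower. Notch1 was among the genes called higher by over 8-fold. For the 8 of those with other kept probes, the other probes changed by a median of 0.03, against 4.41 for the called ones. Complement genes had a median of -0.07 (adjusted p = 0.702) and muscle atrophy and glucocorticoid targets -0.42 (0.141). Medians were, for autophagy genes, -0.03 (0.859), the unfolded protein response -0.23 (0.362), cell cycle genes 0.23 (0.362) and clock genes 0.36 (0.436). Medians of heat shock proteins (0.02, adjusted p = 0.970) and hypoxia inducible genes (0.06, 0.912) were positive while camera placed them lower. Within these lists Cenpa, a centromere histone, rose by 2.12 ± 0.23 and Gadd45a, a growth arrest gene, by 1.54 ± 0.28. Cytosolic ribosomal protein genes had a median of 0.01 (adjusted p = 0.954), but -0.65 with the slide as a block (adjusted p = 1.38e-05; adjusted p = 0.866 with an estimated correlation and the slide as a block), and their median difference was 1.09 between saline 3 and saline 1 and 2 and 0.71 between rhTM 3 and rhTM 1 and 2. Aplnr, Pgf, Notch4 and Gadd45a no longer passed with the slide as a block (adjusted p 0.0719 to 0.0907). In the fit with the replicate number as a block, Aplnr, Pgf, Notch4 and Gadd45a no longer passed (adjusted p 0.0536 to 0.0685).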

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

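The alternative without disagreeing probes was chosen after the data were seen, and the others before. The counts of 405 genes higher and 355 lower became 2205 and 2314 with the deposited value table, 132 and 19 with no filter on dim probes, 4663 and 4581 with array weights, 0 and 0 on the shared slide alone (limma, 2104 and 1681 at unadjusted p under 0.05), 1132 and 877 at unadjusted p under 0.05 with at least 2-fold change, and 1106 and 1259 at adjusted p under 0.1. The higher count became 678 with every probe tested by itself. The deposited table holds a baseline per slide, 22815 genes were tested with no filter, and the shared slide has 1 saline array, but the cause was not tested for any of these counts. Lists called, 4 higher and 11 lower, became 6 higher with the deposited table and with the mean over probes, 21 lower with every probe tested by itself, 7 higher with the slide as a block, 9 higher on the shared slide alone, and 0 and 0 both with an estimated correlation (none at unadjusted p under 0.05) and with fry (5 and 10 at unadjusted p under 0.05). Causes of these changes were not tested. With the replicate number as a block 357 genes higher, 242 lower, 7 lists higher and 15 lower were called. All 15 lists called without the block stayed called, and 31 of the 241 named genes lost their call and 18 gained one.

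Leaving out 1 array at a time gave 0 to 3007 genes higher, 0 to 2808 lower, 3 to 9 lists higher and 7 to 15 lists lower. Genes higher and lower numbered 2 and 0 without saline 1, 55 and 3 without saline 2, 3007 and 2808 without saline 3, 0 and 0 without rhTM 1 (1271 and 1314 at unadjusted p under 0.05), 2 and 0 without rhTM 2, and 382 and 512 without rhTM 3. Lists higher numbered 9 without saline 2 and lists lower 7 without saline 3. Among values that changed sign, ribosomal proteins had a median of -0.65 with the slide as a block and on the shared slide and -0.60 with the deposited table, epicardial markers 1.05 on the shared slide, and Tek 0.67 with the deposited table. The cause was not tested. Quantile normalisation, normexp, the stricter filter, the variance model and the set without disagreeing probes kept all 4 counts within 1.5 times. Of the called lists, acute phase, NF-kB, class II, oxidative phosphorylation, matrix and immediate early genes kept their call in 19 of 21 alternatives chosen before the data were examined, the exceptions being the estimated correlation and fry, while endothelial markers kept theirs in 10. Their medians moved: over those alternatives they were -4.62 to -1.71 for acute phase, -1.80 to -0.96 for NF-kB, 0.82 to 2.50 for class II, 0.20 to 0.68 for oxidative phosphorylation, -0.88 to -0.49 for matrix, -1.25 to -0.58 for immediate early genes and -0.54 to -0.11 for endothelial markers. Signal over background limits the genes at low level, where a fold is a bound.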

Other observations

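Cell type markers beyond those of the inflammatory lists held scattered changes. Among nerve and Schwann cell markers (median 0.48, adjusted p = 0.460) the noradrenaline-synthesising enzyme Dbh rose by 2.40 ± 0.45 and was 3.19 against saline 3, Stmn2 (1.59 ± 0.34, adjusted p = 0.0513) and tyrosine hydroxylase, Th (0.83 ± 0.20, 0.0631), missed the threshold, and Ncmap, a myelin protein well above background on 2 of 3 rhTM arrays, fell by 1.88 ± 0.22. Of the mast cell and dendritic cell markers (median 0.75, adjusted p = 0.0740), the mast cell protease Mcpt4, well above background on 1 of 3 saline arrays, rose by 2.82 ± 0.53. Platelet markers (median 0.54, adjusted p = 0.0558) went both ways, with Gp9 higher (1.57 ± 0.21) and Itgb3 lower (-2.90 ± 0.43). Cytl1, in the lymphatic and endocardial list (median -0.30, adjusted p = 0.576), rose by 2.72 ± 0.54. Mcpt4 and Itgb3 no longer passed once the slide was a block (adjusted p 0.0514 to 0.0520). Blocking on the slide, Stmn2 passed (adjusted p 0.0339).

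Among supporting cells of the vessel wall, the pericyte genes went apart: Rgs5 rose by 1.21 ± 0.24 and Pdgfrb fell by 1.00 ± 0.19 (list median -0.30, adjusted p = 0.362). Laminin gamma-1, Lamc1, fell among the fibroblast markers (-0.91 ± 0.17, list median -0.23, 0.576), with its other probe at 0.06. B and plasma cell (0.62, 0.292), adipocyte (-0.19, 0.636), atrial (0.42, 0.439; 0.0370 with the slide as a block, and adjusted p = 0.866 with an estimated correlation and the slide as a block), epicardial (-0.31, 0.653) and erythroid lists (median -0.06, mean 0.09, 0.860) were not called, and neither were markers of tissues that dissection can carry over (0.17, 0.423). In that last list the skeletal muscle myosin Myh4, not well above background in saline hearts, was at least 2.89-fold higher. When the slide was a block, Rgs5, Pdgfrb and Lamc1 no longer passed (adjusted p 0.0510 to 0.0895). With the replicate number as a block, Rgs5, Pdgfrb and Lamc1 no longer passed (adjusted p 0.0554 to 0.0609).

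The tests that follow were chosen after the results were seen, except the comparison of single probes over all genes called higher and the counts over splits of the arrays. The inflammatory, acute phase and neutrophil lists lay lower with rhTM. Markers of monocytes, macrophages and lymphocytes did not fall with them, at a median of 0.427 over 45 markers. These markers do not tell blood cells from cells of the tissue, and T and NK cell markers lay low, at list means of -2.76 to -1.02. A loss of blood leukocytes thus stays open. Endothelial, fibroblast and pericyte markers lay a median of 1.85 above the 3 lists, which argues against a lower share of muscle RNA in saline hearts as the sole cause. A partial contribution stays open, since sarcomere genes had a median of 0.43. The slide, set against a single saline array, and an effect of rhTM stay open too. On the shared slide the 64 members differed by a median of -2.63 (bootstrap interval over genes -3.57 to -1.91), but they lay a median of 1.19 higher in saline 3 than in saline 1 and 2.

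Without saline 3, when all saline arrays were on slide 1 and all rhTM arrays on slide 2, 3007 genes were called higher and 2808 lower. Saline 3, on slide 2, showed a median of 79.4% of the difference in the higher genes and 65.2% in the lower ones. Bootstrap intervals over genes, all from the 1 mouse of saline 3, were 77.0% to 81.9% and 63.1% to 68.4%, and leave out the spread between mice. A difference between slides or scans may therefore account for much of those calls, though no other array tells the slide apart from the single mouse of saline 3. Over all genes tested, saline 3 correlated less with rhTM 1 and 2 on its own slide (0.924 and 0.923) than with saline 1 and 2 (0.942 and 0.939). The slide alone thus does not order the arrays. For the inflammatory, acute phase and neutrophil lists alone, a milder response in the mouse of saline 3 is argued against, as members lay a median of 1.19 higher there than in saline 1 and 2. Chemokines, neutrophil granule genes and Toll-like receptor components also lay higher (medians 0.69, 1.09 and 0.55). Interferon response, interferon gamma, class I and complement genes lay lower (-0.25, -0.67, -0.69 and -0.22). Of the 15 genes chosen the same way that were lower by over 8-fold, saline 3 showed a median of -5.85% of the difference, against 70.4% in the 208 higher ones. For the 405 and 355 genes called with all arrays this test is void, since calling favours genes whose saline 3 lies with saline 1 and 2, and an effect of rhTM remains open for them.

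Among genes called higher, other probes of the same gene were measured for 87 and changed by a median of 0.774 (bootstrap interval over genes 0.558 to 0.906, as for the intervals below). The called probes of those genes changed by a median of 1.39, so that for the set as a whole single-probe signal and gene signal cannot be told apart. For 8 genes called by over 8-fold, the other probes changed by a median of 0.0274 (-0.762 to 0.523), against 4.41 for the called ones, which is consistent with signal of single probes. For the 79 called by up to 8-fold the median was 0.813 (0.655 to 0.944), against 1.34, and the question stays open. By contrast, other probes of 133 genes called lower changed by a median of -1.01, against -1.18.

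There are 10 ways to split the 6 arrays into 3 and 3, too few for a share under 0.05. For the 405 genes higher and for the 355 lower, 1 split, the real one, gave as many, and the highest count of any other split was 0. For the 4 lists higher, 10 splits gave as many in a direction, and for the 11 lists lower 7 did, with 20 as the highest of the others in both cases. In both directions together the real split called 15 lists and the others 8 to 29. The number of lists called thus does not set the real groups apart. Of the 4 splits that part all 3 pairs of same-numbered arrays, the others called 0 genes and up to 12 lists in a direction.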
